A study of Mus musculus with 11 samples.

How the data were processed

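The series measured RNA of single cells sorted from dorsal skin of young (7 weeks) and aged (88 weeks) C57BL/6 mice, unwounded and at 4 and 7 dpw, with Chromium 3′ kits (v2 or v3) on an Illumina sequencer. There were 11 libraries: 9 of the v3 kit, with 1 young and 2 aged libraries per time, and 2 young 7 dpw libraries of the v2 kit. Per the submitters' processing notes, reads were mapped to mm10 with Cell Ranger 3.1.0 and the libraries of 1 kit and batch were aggregated. The deposited matrices hold the unit count, whole numbers of unique molecular identifiers (UMI) per gene and cell barcode, and the barcode lists of the authors name the library by a suffix. Whether reads were thinned to equal depth in that step is not stated. Among the v2 barcodes, 5 suffixes had no label and were not used here. The labels do not say that each library is a separate animal, so p-values measure only the spread between libraries, and intervals of shares and count ratios cover counting error only.

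The tables held 56695 labelled barcodes, 45917 of them v3, with 3341 to 6520 barcodes, 32894985 to 62116228 UMI and a median of 3019 to 6872 UMI and 920 to 2183 genes per barcode in each library. The v3 gene list has 31053 genes, of which 27514 are in the v2 list of 27998. There were 71 repeated symbols, kept apart by their Ensembl identifiers. Cells with at least 200 genes and under 15% mitochondrial UMI were kept (30175 v3 and 10684 v2 cells). Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold called 35 v3 cells (0.12%), so the highest scores were called at an expected rate of 0.8% per 1000 barcodes, 1393 cells (4.62%).

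The remaining 28782 v3 cells were scaled to equal depth, log-transformed and reduced to 40 principal components of 3000 variable genes, without alignment between libraries. A shared-neighbour graph of 15 neighbours was clustered with leidenalg 0.10.2 at resolution 1 (41 clusters; 59 at resolution 2; seed 0). Clusters took the class whose fixed markers, written down before the data were examined, scored highest. Clusters 25, 27, 30, 37 and 39 stayed unnamed by rules set after the clusters were seen. Arg1 is a fixed macrophage marker, Krt15 a basal and Acta2 a pericyte marker, so their levels also bear on the naming. Cells of the v2 libraries, doublets and cells of the looser filter were placed by nearest neighbours. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.

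Counts were summed per class and library where a library had at least 20 cells of the class. Fibroblast-like cells numbered 406 to 2165 per v3 library (11249138 to 26026664 UMI). Basal keratinocyte-like cells numbered 23 and 27 in the 4 dpw libraries used and 41 to 348 elsewhere, aged 4 dpw replicate 2 (7 cells) being left out. Macrophage-like cells numbered 49 and 23 in the unwounded libraries used (217245 and 166975 UMI) and 286 to 1173 in wounds, aged unwounded replicate 2 (12 cells) being left out. Main fits had 9, 8 and 8 libraries and 4, 3 and 3 residual degrees of freedom. Genes were tested two-sided with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM) with time, age and batch as terms, and p-values were adjusted by Benjamini and Hochberg at 0.05.

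The batch term stands for the table. The labels number the aged replicates by batch, and all young v3 libraries lie in batch 2, so age is estimated within batch 2. As a check of the pairing, the log2 differences between batches of the aged fibroblast-like cells, over 14503 genes with a pseudocount of 1 CPM, correlated at 0.15, 0.02 and 0.35 between pairs of times. Fits without this block are among the alternatives. The interaction was tested on both of its terms together, with 2, 1 and 1 residual degrees of freedom. Class shares were tested with edgeR on cell counts offset by the cells of the library. Exact permutations of age within time, without regard to batch (27 arrangements), and of times within age and batch (216 arrangements) were run beside it. For the times, swapping the 2 compared times throughout only reverses the sign of the difference, so the smallest two-sided p is 0.00926.

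Lists of genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation. The 24 lists, fixed before the data were examined, were inflammatory cytokines and chemokines, repair-type macrophage, MHC class II presentation, MHC class I presentation, interferon-stimulated, fibrillar matrix, matrix remodelling, myofibroblast, fibroblast chemokines and cytokines, reticular and universal fibroblast, papillary fibroblast, complement, wound keratinocyte, basal adhesion, epidermal differentiation, cell cycle, senescence and its secretory genes, glycolysis and hypoxia, oxidative phosphorylation, dissociation and immediate early, growth factor ligands, receptors, haemoglobin, and sex-linked genes, the last with under 4 measured members and no list test. Genes were also adjusted over each list alone, and members named from that were chosen after the values were seen.

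Genes were named by a rule fixed before the data were examined. Per class and contrast these were the 6 largest rises and 6 largest falls at adjusted p < 0.05 with a mean log2 CPM of at least 5, the same sign in every fit without 1 library, and at least 10% of the level in the class where the gene is highest. Predicted, ribosomal protein and mitochondrial genes and class markers were left out. Up to 4 called members per list by smallest p were added, and, whatever their p, Il1b, Arg1, Mrc1, Cxcl2 and Ccl2 in macrophage-like, Krt6a, Krt16 and Krt17 in basal keratinocyte-like, and Col1a1, Col3a1, Acta2, Ccl2, Cdkn2a and Cdkn1a in fibroblast-like cells. Where 1 group had 0 counts, the fold is a floor from 3 counts, and where it had 1 to 3 counts, the ratio carries a 95% counting interval. Another 8 classes were fitted, and 3 of them are described after their values were seen.

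Alternatives were DESeq2 1.42.0 (test and size factors), no filter on low counts, no batch block, 500 genes and 10% mitochondrial UMI, doublets kept, thinned depth, resolution 2, genes under 10% of their highest class left out, batch 2 alone, the v2 libraries added and each library left out. Chosen after seeing the data were a 30% mitochondrial filter, fits without cluster 19 (564 cells) and fits without cluster 15 (730 cells). In simulated data with 200 changed genes, 28% of 2-fold and 79% of 4-fold age changes were recovered in fibroblast-like cells (119 called, 12 of them false), 29% and 80% in basal keratinocyte-like cells (121 called, 12 false) and 1% and 48% in macrophage-like cells (58 called, 9 false). For the wound contrasts of macrophage-like cells 0% of 2-fold and 12 to 13% of 4-fold changes were recovered, against 28 to 30% and 73 to 74% in fibroblast-like cells.

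Positions are from GENCODE vM21 on GRCm38 (mm10). Cxcl5 (ENSMUSG00000029371) lies at chr5:90759360-90761624, Saa3 (ENSMUSG00000040026) at chr7:46711998-46715700, Timp1 (ENSMUSG00000001131) at chrX:20870166-20874735, Tnc (ENSMUSG00000028364) at chr4:63959785-64047015 and Cthrc1 (ENSMUSG00000054196) at chr15:39076932-39087121. Tmod1 (ENSMUSG00000028328) lies at chr4:46038935-46116032, Gjb2 (ENSMUSG00000046352) at chr14:57098600-57104702, Arg1 (ENSMUSG00000019987) at chr10:24915221-24927484, Serpinb2 (ENSMUSG00000062345) at chr1:107511423-107535478, Mgl2 (ENSMUSG00000040950) at chr11:70130329-70137550 and Cdkn2a (ENSMUSG00000044303) at chr4:89274471-89294653.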

Results

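Dorsal skin of young (7 weeks) and aged (88 weeks) C57BL/6 mice was compared without a wound and at 4 and 7 days post wounding (dpw) to find which cell classes and which of their genes changed with the wound and with age. Values are means ± standard deviation over libraries, n counts libraries, and log2 fold changes (log2 FC) carry standard errors. Adjusted p-values are two-sided, from edgeR for genes and shares and from camera of limma for lists, unless another tool is named. The wound contrasts average both ages. The age contrast is shared over the 3 times and estimated within batch 2, which holds every young v3 library. Aged means and their n also count the batch 1 libraries. Where an aged batch 2 library was left out, that time has no young and aged pair in 1 batch.

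The wound filled with myeloid cells, which enter skin wounds in the first days, while the share of epidermal cells fell. Neutrophil-like cells rose from 0.0992 ± 0.0441% of cells in unwounded skin to 26.4 ± 6.61% at 4 dpw (n = 3 and 3; log2 FC 8.02 ± 0.69, adjusted p = 8.23e-05). They stood at 10.3 ± 6.22% at 7 dpw (n = 3; 6.56 ± 0.66, adjusted p = 0.000293), with 16.85 and 9.44% in the aged and 4.5% in the young library of the v3 kit. The young 7 dpw libraries of the v2 kit, which this fit leaves out, held only 0.25 and 0.33%. Macrophage-like cells rose from 0.733 ± 0.463% to 29.6 ± 2.83% at 4 dpw (5.48 ± 0.47, adjusted p = 8.23e-05) and 13.2 ± 5.57% at 7 dpw (4.22 ± 0.44, adjusted p = 0.000293). Basal keratinocyte-like cells fell from 5.80 ± 2.59% to 0.672 ± 0.326% at 4 dpw (-3.12 ± 0.37, adjusted p = 0.000395) and to 1.56% at 7 dpw (-1.84 ± 0.34, adjusted p = 0.00423). At 4 dpw the shares of spinous keratinocyte-like (-2.75 ± 0.40, adjusted p = 0.00112), hair follicle keratinocyte-like (-2.14 ± 0.43, adjusted p = 0.00557) and fibroblast-like cells (-0.98 ± 0.29, adjusted p = 0.0283) fell as well. Pericyte-like or smooth muscle-like cells rose at 7 dpw, from 0.771% to 4.19 ± 2.34% (2.54 ± 0.42, adjusted p = 0.00305). These are 6 of 14 classes at 4 dpw and 4 at 7 dpw. The exact permutation of the shares called the same 6 classes at 4 dpw, and also T-cell-like (adjusted p = 0.0486) and dendritic-like cells (adjusted p = 0.037). It called 0 classes at 7 dpw. Its arrangements move the libraries of all 3 times, so it tests neither wound time alone. The 6 calls at 4 dpw became 10 with the doublets kept or without aged 7 dpw replicate 1. Shares are fractions of sorted cells, so a rise of one class lowers the others.

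Age changed the share of 0 of 14 classes, with 2 at unadjusted p < 0.05 by edgeR. Hair follicle keratinocyte-like cells made up 10.7 ± 6.93% of aged (n = 6) and 4.08 ± 2.14% of young libraries (n = 3; log2 FC 1.30 ± 0.42, adjusted p = 0.271). Dendritic-like cells made up 3.63 ± 0.772% and 5.82 ± 1.40% (-0.59 ± 0.24, adjusted p = 0.333). An exact permutation within each time, which has 27 arrangements and a smallest possible two-sided p of 0.037, reached 0.037 for 4 classes: dendritic-like (-2.19 percentage points), fibroblast-like (-13.54), hair follicle keratinocyte-like (6.61) and pericyte-like cells (-1.58), each with adjusted p = 0.13. Unlike the edgeR fit, that permutation disregards the batch, so its differences also count the aged batch 1 libraries. For the difference of the wound response between ages, 0 of 14 classes were called by edgeR (adjusted p = 0.951 for every class).

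**Figure D1:**
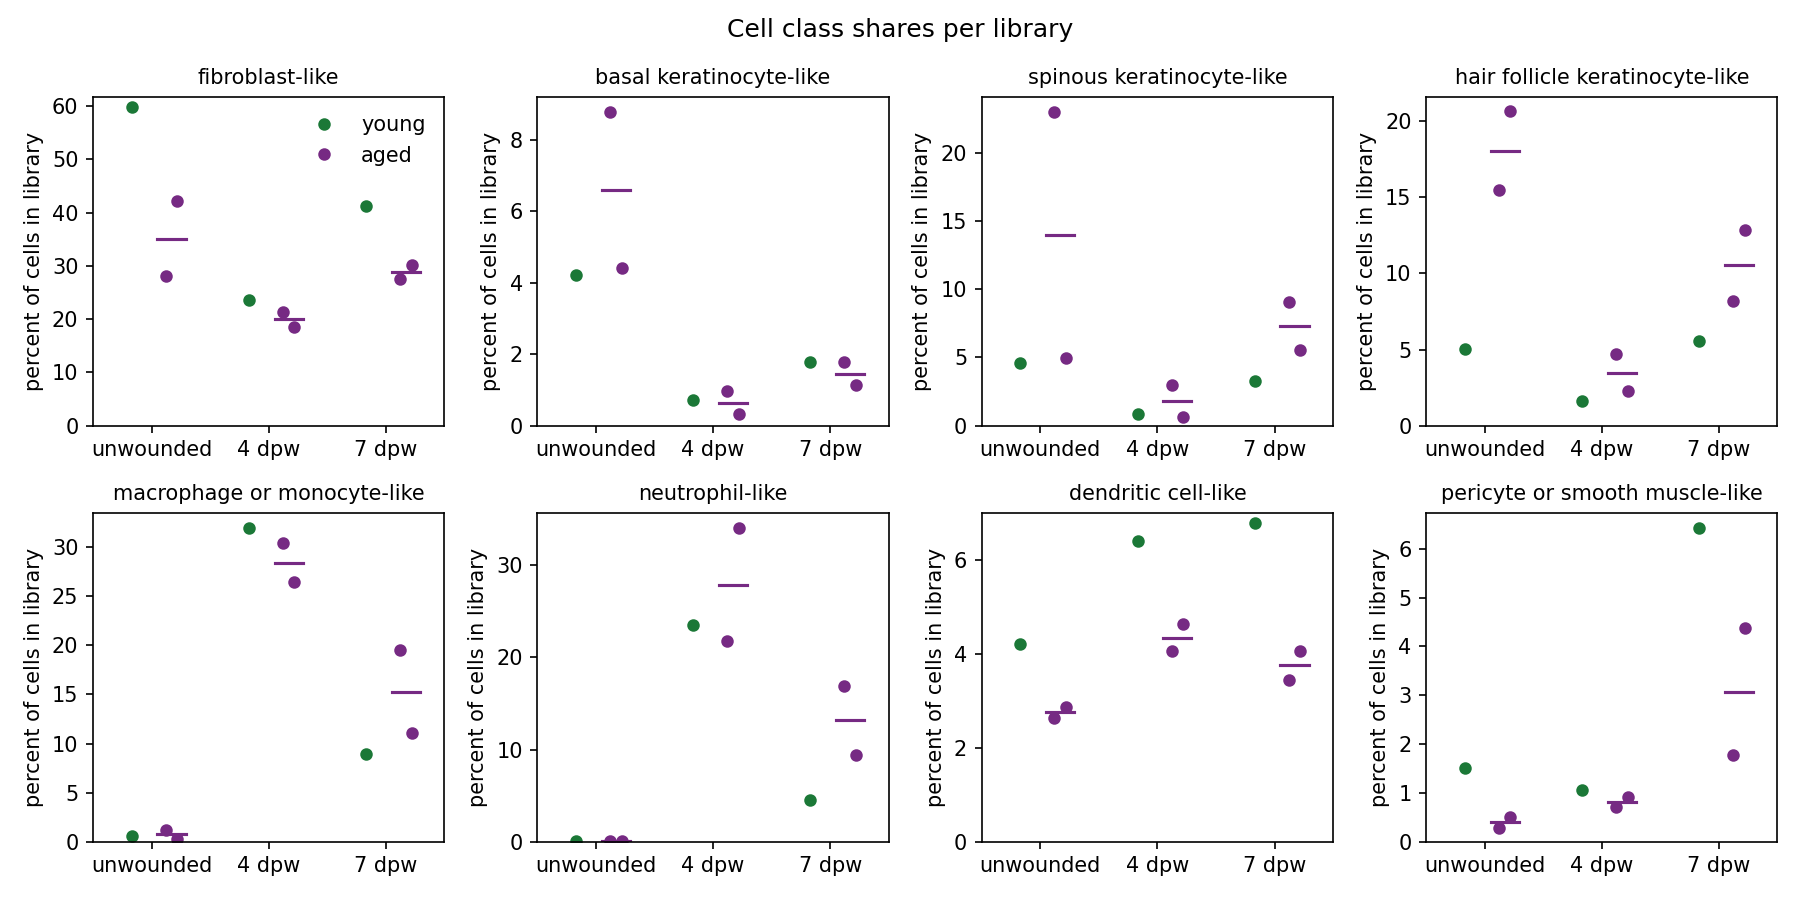
Share of the named cell classes in each library of the v3 chemistry; green, young; purple, aged; the line is the mean of the 2 aged libraries.

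Fibroblast-like cells of the 4 dpw wound expressed more Cxcl5, Saa3, Timp1 and Tnc, which wound-edge fibroblasts are known to express, and less Myoc and Ltbp4. Cxcl5 rose from 0.86 ± 1.42 to 947 ± 292 CPM (normalised count rates; n = 3 and 3; log2 FC 10.92 ± 1.07, adjusted p = 0.00132), and Saa3 from 4.87 ± 5.23 to 3410 ± 1560 CPM (9.65 ± 1.26, adjusted p = 0.00275). Timp1 rose from 73.5 ± 24.3 to 2390 ± 979 CPM (5.13 ± 0.57, adjusted p = 0.00165). Tnc rose from 18.8 ± 12.6 to 1580 ± 930 CPM (6.60 ± 0.55, adjusted p = 0.000951), and Cthrc1 from 18.5 ± 17.7 to 781 ± 81.8 CPM (5.85 ± 0.80). Falls were of Myoc (-3.28 ± 0.66, adjusted p = 0.0106), Ltbp4 (328 ± 128 to 38.1 ± 17.5 CPM, -3.19 ± 0.32), Kazald1 (-3.03), Aldh3a1 (-3.00), Oxtr (-2.97) and Ecm2 (-2.78 ± 0.51). In all, 4869 of 14503 tested genes changed (2591 up, 2278 down), 2782 of them by 2-fold or more. Hp (9.02 ± 0.94), Car4 (8.48 ± 0.50), Rnd1 (7.78 ± 0.73) and Serpinb2 (7.77 ± 0.89, 3.32 ± 1.38 to 708 ± 321 CPM) rose as well.

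Chemokine and cytokine genes were among the rises at 4 dpw. All 18 measured members of the inflammatory cytokine and chemokine list rose (median log2 FC 4.94, list adjusted p = 3.89e-13), with Ptgs2 at 4.68 ± 0.24. That list was no longer called with an estimated correlation between genes (adjusted p = 0.258 with an estimated correlation). Cxcl3 (10.0), Clec4e (7.80), Il1b (3.67) and Tnf (5.17) rose too, but stood at 2.11, 0.162, 0.0706 and 0.491% of the class where each is highest, so their reads can come from free RNA of myeloid cells. Of the fibroblast chemokines and cytokines, 13 of 17 rose and 1 fell (adjusted p = 1.27e-05; adjusted p = 0.258 with an estimated correlation; 13 and 2 when adjusted over the list alone). Among them Ccl2 rose from 493 ± 196 to 3440 ± 888 CPM (2.86 ± 0.19, adjusted p = 0.0006) and Cxcl1 from 113 ± 16.6 to 3100 ± 415 CPM (4.71 ± 0.49). Il6 rose as well (2.13 ± 0.22). Of 40 growth factor ligands, 12 rose and 10 fell (median -0.05 and mean 0.82, list test up, adjusted p = 0.681). Bmp4 fell from 83.1 ± 15.5 to 12.4 ± 2.81 CPM (-2.77 ± 0.37) and Bmp7 fell (-1.90). Of 39 receptors, 10 rose and 4 fell (adjusted p = 0.38), Osmr (1.36) and Il1r1 (1.21) among the rises. The repair-type macrophage list had 6 rises and 3 falls of 18 in these cells (adjusted p = 0.0242; adjusted p = 0.394 with an estimated correlation), Spp1 rising by 5.45 ± 1.05.

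Members of both matrix lists rose. Of 18 matrix remodelling genes 9 rose and 2 fell (adjusted p = 0.00412; adjusted p = 0.528 with an estimated correlation), among them Timp1, Tnc and Mmp19 (2.13). Of 22 fibrillar matrix genes 8 rose and 2 fell (adjusted p = 0.0446; adjusted p = 0.718 with an estimated correlation). Lox went from 150 ± 35.4 to 931 ± 129 CPM (2.65 ± 0.21), with Col12a1 (2.46) and Col5a2 (1.12) also up, while Col1a1 (-0.27, adjusted p = 0.473) and Col3a1 (0.40, adjusted p = 0.382) were not called. Of 16 myofibroblast genes 8 rose (median 1.19, adjusted p = 0.00102; adjusted p = 0.718 with an estimated correlation), among them Runx1 (2.38) and Cthrc1, and Acta2 was not called (2.33, adjusted p = 0.159). Papillary fibroblast genes fell, 8 of 12 against 1 that rose (median -1.43, adjusted p = 0.0228; adjusted p = 0.718 with an estimated correlation), as Apcdd1 (-2.17), Trps1 (-1.81) and Axin2 (-1.91 ± 0.38) did. Reticular and universal genes split into 5 rises and 6 falls of 16 (median -0.06 and mean 0.44, list test down, adjusted p = 0.899), with Sfrp2 up (4.59 ± 0.50) and Pi16 down (-1.87 ± 0.25).

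Members of the cell cycle and glycolysis lists rose too. Of 23 cell cycle genes 18 rose (median 3.52, adjusted p = 2.12e-09; adjusted p = 0.53 with an estimated correlation), such as Birc5 (5.91 ± 0.52), Ccnb1 (6.26 ± 0.56), Ccna2 (4.86) and Tpx2 (4.50). Of 21 glycolysis and hypoxia genes 15 rose (median 1.34, adjusted p = 7.65e-07; adjusted p = 0.258 with an estimated correlation), such as Pgk1 (1.97 ± 0.17), Ldha (1.56) and Hif1a (2.11 ± 0.21). Oxidative phosphorylation (6 rose of 23, median 0.26, adjusted p = 0.00803) and dissociation and immediate early genes (10 of 24, median 0.40, adjusted p = 0.0056) also moved up, both lost with an adjusted p = 0.718 with an estimated correlation. MHC class I presentation fell, 5 of 9 (median -0.85, adjusted p = 0.0056; adjusted p = 0.718 with an estimated correlation), with Psmb9 (-1.24), Psmb8 (-0.97 ± 0.13) and H2-K1 (-0.94 ± 0.23). MHC class II presentation (median -0.25, adjusted p = 0.38), interferon-stimulated (3 rose, 2 fell of 21, adjusted p = 0.681) and complement genes (4 rose, 3 fell of 14, adjusted p = 0.855) were not called as lists. Nor were senescence and its secretory genes (6 rose, 4 fell of 19, adjusted p = 0.38), basal adhesion (3 rose, 7 fell of 15, adjusted p = 0.243), epidermal differentiation (2 rose, 6 fell of 13, adjusted p = 0.211) and haemoglobin (0 of 4, adjusted p = 0.514).

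The wound keratinocyte list rose in these cells too, 15 of 21 (median 2.49 and 2.44 with low-count genes at their bound, adjusted p = 0.000182; adjusted p = 0.347 with an estimated correlation), through Cd44 (3.16 ± 0.24), Itga5 (2.49) and Sdc1 (2.04). Cdkn1a fell (-1.25 ± 0.25, adjusted p = 0.0107). Both measured sex-linked genes, Xist (-0.83, adjusted p = 0.0182) and Tsix (-0.62, adjusted p = 0.0472), fell. The 4869 calls became 1640 in batch 2 alone, 1987 without young 4 dpw replicate 1, 1989 without aged 4 dpw replicate 1, 2606 without aged 4 dpw replicate 2 and 2656 without aged unwounded replicate 1. The fibroblast clusters differed between groups. Cluster 2 held 68.5, 45.8 and 47.7% of these cells at 4 dpw in aged replicates 1 and 2 and the young library. Clusters 8 and 4 (38.2 and 33.4%) held most in young unwounded skin, clusters 6 and 4 (36.7 and 19.8%) and clusters 7 and 4 (33.4 and 24.6%) in aged unwounded replicates 1 and 2.

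At 7 dpw, when a mouse wound is forming granulation tissue, the inflammatory genes Cxcl5 and Saa3 of fibroblast-like cells were still far above unwounded skin. Cxcl5 stood at 490 ± 340 CPM (log2 FC 9.56 ± 1.03, adjusted p = 0.00312; n = 3 and 3) and Saa3 at 2050 ± 1560 CPM (8.49 ± 1.22). Tnc stood at 1110 ± 370 CPM (6.11 ± 0.54) and Cthrc1 at 904 ± 336 CPM (5.93 ± 0.79). Csf2 rose from 0.608 ± 0.402 to 42.3 ± 22.0 CPM (6.19 ± 0.34, adjusted p = 0.00105), and Hpgd fell from 163 ± 6.18 to 26.9 ± 7.45 CPM (-2.63 ± 0.16, adjusted p = 0.00105). Mmp10 had 731 counts against 0, at least 208-fold more. In all 2904 genes changed (1773 up, 1131 down), 1750 by 2-fold or more. Further rises were of Hp (7.75), Rnd1 (6.91), Serpinb2 (6.55), Spp1 (5.97) and Hbegf (3.05 ± 0.45), and further falls of Aldh3a1 (-2.90), Myoc (-2.79), Oxtr (-2.74), Serpina3c (-2.61) and Cadm3 (-2.52). The contrast compares different clusters here too: cluster 2, with Cthrc1, Cxcl5, Saa3 and Tnc among its leading genes, held 67.2, 56.8 and 24.1% of these cells at 7 dpw in aged replicates 1 and 2 and the young v3 library, and at most 0.4% in unwounded skin.

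The lists at 7 dpw moved as follows. Inflammatory genes rose in 17 of 18 (median 4.36, adjusted p = 2.68e-13), fibroblast chemokines in 10 of 17 with 2 falls (adjusted p = 0.000163), wound keratinocyte genes in 14 of 21 (adjusted p = 2.58e-06) and glycolysis in 13 of 21 (adjusted p = 1.37e-05). For these 4 lists the adjusted p = 0.295 with an estimated correlation. Myofibroblast genes rose in 7 of 16 (median 1.71, adjusted p = 1.21e-05; 10 when adjusted over the list alone), fibrillar matrix in 8 of 22 with 1 fall (median 0.71, adjusted p = 0.00218) and cell cycle in 14 of 23 (median 2.85, adjusted p = 3.82e-08). Dissociation genes rose in 10 of 24 (adjusted p = 1.76e-05) and MHC class I genes fell in 5 of 9 (median -0.89, adjusted p = 0.000508). For these 5 lists the adjusted p = 0.473 with an estimated correlation. Matrix remodelling (8 up, 1 down of 18, adjusted p = 0.00123; adjusted p = 0.443 with an estimated correlation) rose as well. So did repair-type genes (5 up, 1 down of 18, adjusted p = 0.0223; adjusted p = 0.383 with an estimated correlation) and oxidative phosphorylation (1 of 23, adjusted p = 0.0139; adjusted p = 0.729 with an estimated correlation). Papillary genes were not called as a list (2 up, 5 down of 12, median -0.98, adjusted p = 0.0749). Bgn (0.98 ± 0.18), Col12a1 (2.70), Col5a2 (1.19) and Lox (1.86) rose. Col1a1 (0.16, adjusted p = 0.71), Col3a1 (0.71, adjusted p = 0.175) and Acta2 (adjusted p = 0.145) were not called. The count was 129 in batch 2 alone, 832 without aged 7 dpw replicate 2, 956 without aged 7 dpw replicate 1, 1085 without aged unwounded replicate 1, 1699 without aged 4 dpw replicate 1 and 1841 without aged unwounded replicate 2.

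**Figure D2:**
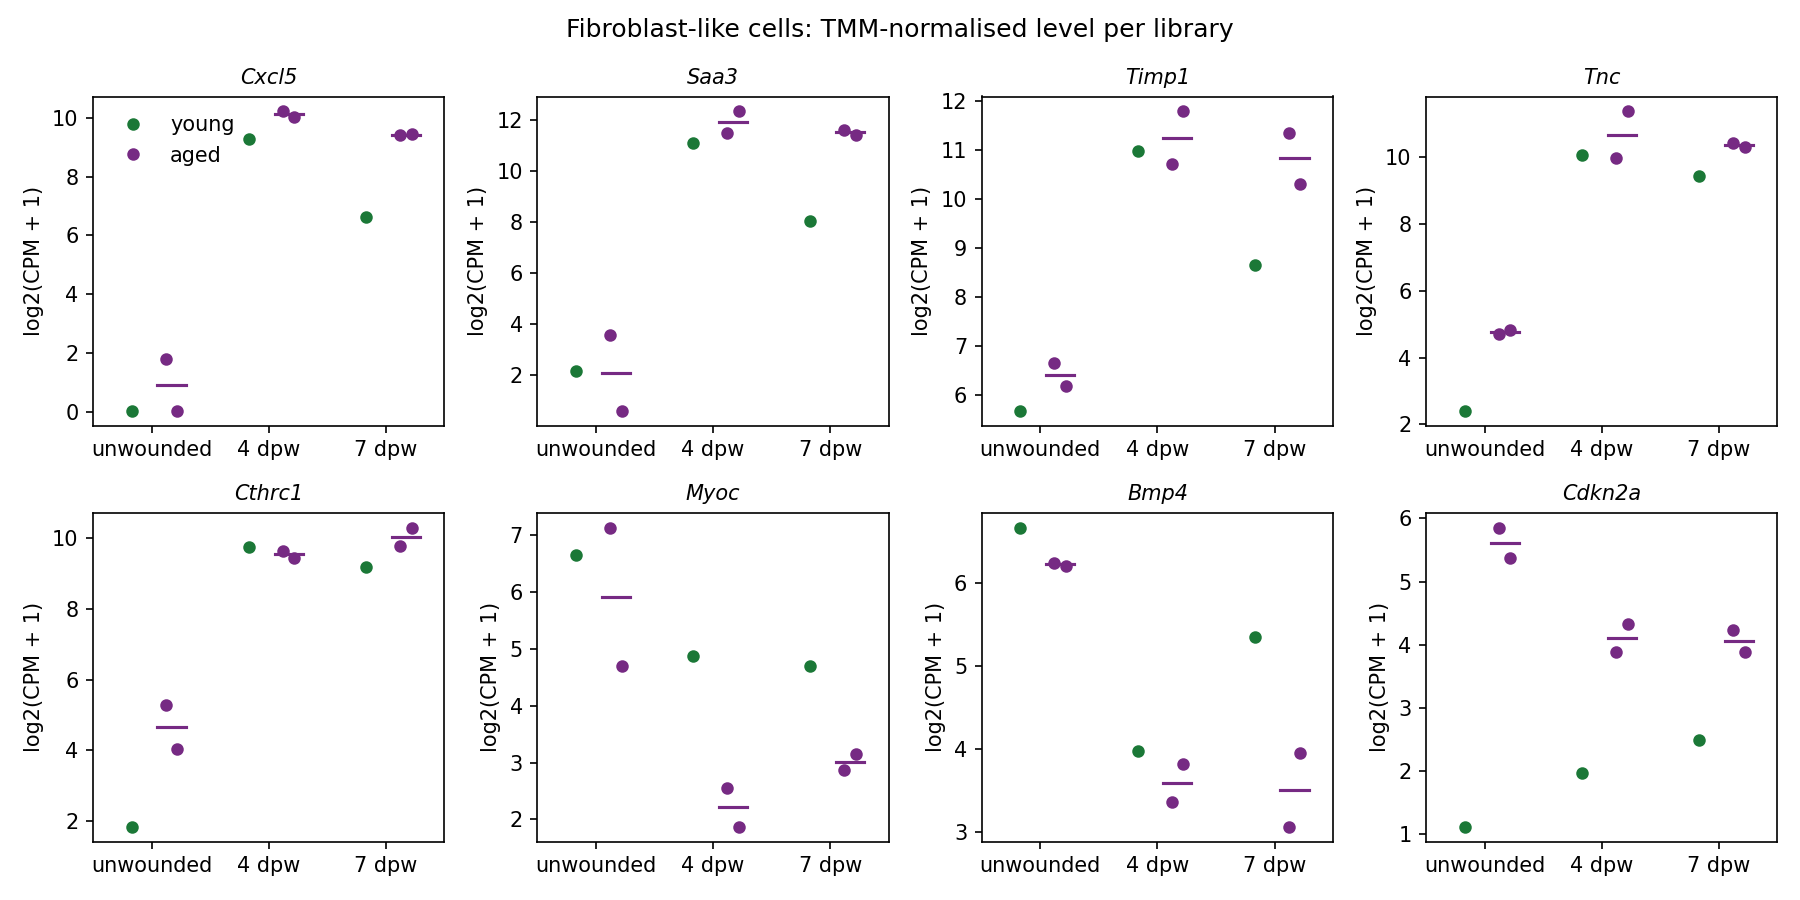
Levels of 8 genes in fibroblast-like cells of each v3 library; green, young; purple, aged; the line is the mean of the 2 aged libraries.

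With age, 1 gene of fibroblast-like cells was called, Tmod1, and 12 of 23 lists, 0 of them with an estimated correlation. Tmod1, which caps actin filaments, fell from 14.3 ± 4.77 CPM in young (n = 3) to 2.99 ± 0.658 CPM in aged libraries (n = 6; log2 FC -2.51 ± 0.20, adjusted p = 0.0445). Its level is low, 4.36% of the class where it is highest, and it is named because the count is 1. The cell cycle inhibitor Cdkn2a, often raised in aged tissue, stood at 26.9 ± 17.7 against 2.91 ± 1.73 CPM and was not called (2.83 ± 0.67, adjusted p = 0.292). Col1a1 was not called either (20900 ± 5800 against 30600 ± 4930 CPM, -0.64 ± 0.28, adjusted p = 0.512). Nor were Col3a1 (-0.52 ± 0.34, adjusted p = 0.652), Ccl2 (0.53 ± 0.18, adjusted p = 0.439), Acta2 (1.60 ± 1.14, adjusted p = 0.668) and Cdkn1a (-0.18 ± 0.24, adjusted p = 0.838). At unadjusted p < 0.05 there were 1424 genes. The DESeq2 test called 230, a fit without a filter on low counts 48 and a fit without the batch block 40. With the v2 libraries the count was 6. It was 0 with thinned depth, at resolution 2, with free RNA genes left out, in batch 2 alone and without any 1 library other than young 7 dpw replicate 3, where the 1 gene called was not Tmod1.

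The reticular and universal list fell (median log2 FC -0.58, adjusted p = 0.000408; adjusted p = 0.259 with an estimated correlation). Adjusted over the list alone 7 members fell, named after the values were seen: among them Clec3b (-1.72 ± 0.42), Anxa3 (-1.22), Gpx3 (-1.15 ± 0.37), Cd34 (-1.15), Ly6c1 (-1.07) and Ly6a (-0.70). Shares of 37 clusters were tested too, in a test chosen after the values were seen. Fibroblast clusters 8 (-4.60 ± 0.81, adjusted p = 0.0221), 18 (-2.39 ± 0.57, adjusted p = 0.0393) and 4 (-2.36 ± 0.58, adjusted p = 0.0393) had lower shares with age. The exact permutation gave each of them 0.037, the smallest possible p of its 27 arrangements, with adjusted p = 0.171. At that floor the adjusted p can pass only if most of the 37 clusters reach it. Follicle cluster 21 was the only other call, with a higher share (6.00 ± 1.41, adjusted p = 0.0393; 0.456 by exact permutation). Gpx3 is among the leading genes of cluster 4, so the fall of the list and the lower share of that cluster are not separate results. Interferon-stimulated (median -0.39, adjusted p = 0.000793; adjusted p = 0.634 with an estimated correlation), MHC class I (-0.29, adjusted p = 0.0281; adjusted p = 0.679 with an estimated correlation) and haemoglobin genes (-2.95, adjusted p = 0.0233; adjusted p = 0.634 with an estimated correlation) fell. Glycolysis and hypoxia rose (median 0.49, 20 of 21 members positive, adjusted p = 4.64e-07; adjusted p = 0.259 with an estimated correlation), with Tpi1 called over the list alone (0.64 ± 0.12). The cell cycle list rose with 23 of 23 members positive (median 0.71, adjusted p = 8.9e-05). So did inflammatory genes (median 0.50, adjusted p = 0.00755), senescence genes (0.26, adjusted p = 0.0427) and epidermal differentiation (0.99, adjusted p = 0.00237). Each of these 4 lists had an adjusted p = 0.634 with an estimated correlation. Myofibroblast genes rose (0.78, adjusted p = 0.0101; adjusted p = 0.679 with an estimated correlation). Wound keratinocyte genes (0.89, adjusted p = 5.96e-06; adjusted p = 0.259 with an estimated correlation) and basal adhesion (0.44, adjusted p = 0.00095; adjusted p = 0.478 with an estimated correlation) rose, where Krt14 (1.52) and Krt6a (3.77) stood at 0.0686 and 0.142% of their highest class.

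The other lists were not called for age in fibroblast-like cells. They were repair-type macrophage (adjusted p = 0.533), MHC class II (0.623), fibrillar matrix (median -0.20, adjusted p = 0.0969), and matrix remodelling (0.335). Further ones were fibroblast chemokines (0.367), papillary (0.0969), complement (0.167), oxidative phosphorylation (0.239), dissociation (0.195), growth factor ligands (0.351) and receptors (median 0.05 and mean 0.09, list test down, adjusted p = 0.972). Adjusted over single lists, and chosen after the values were seen, Ptgs2 (1.10 ± 0.21, 414 against 180 CPM) and Crabp1 (1.02) rose, and Timp3 (-2.02 ± 0.32, 204 ± 145 against 753 ± 602 CPM) and Csf1 (-1.01) fell. Timp3 is among the leading genes of cluster 4, whose share fell, and Crabp1 of cluster 15, whose share was not called (1.48 ± 0.54, adjusted p = 0.0978), and neither was tested within a cluster.

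Basal keratinocyte-like cells of the 7 dpw wound had more reads of the cystatin genes Stfa1 and Stfa3 and expressed less Krt15, a fixed marker of their class that falls in wound-edge epidermis. Stfa1 rose from 1.20 ± 0.76 to 207 ± 283 CPM (n = 3 and 3; log2 FC 7.22 ± 0.56, adjusted p = 0.000215) and Stfa3 from 13.6 ± 5.96 to 772 ± 339 CPM (5.76 ± 0.48, adjusted p = 0.000319). Both are among the leading genes of spinous cluster 26, whose share rose at 7 dpw (4.62, adjusted p = 0.000715), and stood at 11.74 and 14.61% of the spinous class, so a contribution of spinous cells was not excluded. The neutrophil genes S100a8 (56 against 0 counts, at least 64.7-fold more) and S100a9 (53 against 3 counts, 61.2-fold, interval 19.9 to 306) rose too, at 0.01603 and 0.01042% of the neutrophil class, a level that free RNA can give. Gpha2 fell from 136 ± 58.5 to 19.5 ± 9.96 CPM (-2.70 ± 0.34, adjusted p = 0.00398) and Wnt16 from 103 ± 40.9 to 33.4 ± 2.41 CPM (-1.55 ± 0.24). Cxcl14 fell from 1090 ± 200 to 404 ± 206 CPM (-1.51 ± 0.32, adjusted p = 0.0493) and Krt15 from 8740 ± 3780 to 3480 ± 1830 CPM (-1.36 ± 0.18, adjusted p = 0.00448). Nppb (4.31 ± 0.80, adjusted p = 0.0442), Lypd3 (1.98 ± 0.37), Cwh43 (1.86), Capn2 (1.84 ± 0.23) and Hk2 (1.22, adjusted p = 0.0493) rose. Bbox1 (-1.51), Il34 (-1.50), Sh3d21 (-1.43), Nr4a1 (-1.42), Cd55 (-1.37), Btg2 (-1.26), Atf3 (-1.19 ± 0.12, adjusted p = 0.000943), Junb (-1.12) and Sdc4 (-1.04) fell. In all 96 of 8150 genes changed (55 up, 41 down). Krt6a went from 7.66 ± 6.68 to 838 ± 1310 CPM without passing (5.80 ± 1.41, adjusted p = 0.0746), and Krt16 (1.99, adjusted p = 0.291) and Krt17 (0.32, adjusted p = 0.652) did not pass.

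The wound keratinocyte list rose in 7 of 21 members at 7 dpw (10 when adjusted over the list alone; median 1.03, adjusted p = 1.02e-06). The myofibroblast list rose in 5 of 7 (median 2.59, adjusted p = 4.85e-08). Both had an adjusted p = 0.105 with an estimated correlation. Many of those rises stand at levels that free RNA can give: Postn (2.75) at 6.05%, Mmp13 (4.47) at 4.07%, Tnc (3.14) at 1.73% and Acta2 (3.15) at 0.377% of their highest class. The cell cycle list rose (0 of 23 called, 6 adjusted over the list alone; median 0.88, adjusted p = 1.08e-06; adjusted p = 0.521 with an estimated correlation), with Mki67 at 1.34, Mcm5 at 1.24 and Top2a at 1.14. The dividing cluster of the class, 36, held 31.8, 26.8 and 15.8% of its cells at 7 dpw (aged replicates 1 and 2, young v3) against 4.3, 16.8 and 9.2% unwounded, so that rise is not separate from the cluster mix. Dissociation and immediate early genes fell, 7 against 3 that rose of 24 (median -0.61, adjusted p = 0.0128; adjusted p = 0.324 with an estimated correlation). Fibrillar matrix (4 of 16, adjusted p = 0.000285; adjusted p = 0.443 with an estimated correlation), and inflammatory genes (1 of 10, adjusted p = 0.0235; adjusted p = 0.443 with an estimated correlation) rose. So did remodelling (1 of 9, adjusted p = 0.0164; adjusted p = 0.521 with an estimated correlation) and glycolysis genes (1 of 19, adjusted p = 0.0142; adjusted p = 0.516 with an estimated correlation). The 96 calls became 23 without the batch block, 558 without a filter on low counts, 52 with thinned depth, 179 in batch 2 alone and 194 with the v2 libraries. They became 25 without young unwounded replicate 1, 26 without aged unwounded replicate 1, 59 without young 7 dpw replicate 3 and 153 without aged 7 dpw replicate 1.

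At 4 dpw, a time when new epidermis migrates over a mouse wound, the basal class was small and 26 genes changed (20 up, 6 down). Ncapd2 rose from 22.7 ± 10.2 to 64.8 ± 5.97 CPM (n = 3 and 2; log2 FC 1.83 ± 0.31). So did Prrg4 (15.1 ± 7.23 to 70.1 ± 68.7 CPM, 2.45 ± 0.42, adjusted p = 0.0368), Actn1 (1.79 ± 0.29), Tmcc3 (1.75), Ggct (1.71) and Csrp2 (1.54). Dusp1 fell from 659 ± 139 to 286 ± 50.6 CPM (-1.32 ± 0.22, adjusted p = 0.0332), Junb from 2250 ± 300 to 1240 ± 170 CPM (-0.94 ± 0.14, adjusted p = 0.0304). Krt15 (-1.22 ± 0.21, adjusted p = 0.0368), Nfkbia (-1.04 ± 0.17) and Sdc4 (-0.95) fell. Krt6a (3.98 ± 1.82, adjusted p = 0.417), Krt16 (-0.80, adjusted p = 0.779) and Krt17 (1.17, adjusted p = 0.226) were not called. The cell cycle list rose (0 of 23 called, median 0.84, adjusted p = 0.00195; adjusted p = 0.71 with an estimated correlation), and cluster 36 held 21.7 and 22.2% of the class in the fitted 4 dpw libraries, so neither this rise nor that of Ncapd2 was tested apart from the mix. So did the inflammatory list (2 of 10, adjusted p = 7.44e-06; adjusted p = 0.291 with an estimated correlation). Its called members Cxcl2 (4.95) and Tnf (2.98) stood at 0.0228 and 0.667% of their highest class. The dissociation list fell (2 of 24, adjusted p = 0.0179; adjusted p = 0.291 with an estimated correlation). The count was 41 by DESeq2, 307 without a filter on low counts, 3 without the batch block, 2 with thinned depth and 16 with free RNA genes left out. It was 2 without aged 4 dpw replicate 1 or aged unwounded replicate 1, 4 without young 4 dpw replicate 1, and 6 without young unwounded replicate 1. It was 42 without aged unwounded replicate 2, 43 without young 7 dpw replicate 3, 51 without aged 7 dpw replicate 2 and 137 without aged 7 dpw replicate 1.

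With age, basal keratinocyte-like cells had more reads of the gap junction gene Gjb2 and expressed more of the inflammatory caspase gene Casp4. Gjb2 rose from 2.24 ± 3.49 CPM in young (n = 3) to 101 ± 81.2 CPM in aged libraries (n = 5; log2 FC 6.39 ± 1.02, adjusted p = 0.0245). It stood at 17.01% of the hair follicle class and is among the leading genes of follicle cluster 31, which held 0 cells of the young unwounded library, so a contribution of follicle cells was not excluded. Casp4 rose from 23.2 ± 9.76 to 113 ± 25.2 CPM (2.29 ± 0.29) and Pxdc1 from 51.5 ± 24.1 to 251 ± 96.2 CPM (2.40 ± 0.31, adjusted p = 0.00852). Noct (2.29 ± 0.38), Pmepa1 (24.6 ± 1.15 to 92.5 ± 35.6 CPM, 2.14 ± 0.27) and Tmcc3 (2.07 ± 0.30) rose too. Arrdc3 (-1.28 ± 0.23, adjusted p = 0.0428) and Rgcc (-1.70 ± 0.29, adjusted p = 0.0309) fell. In all 36 genes changed (34 up, 2 down). Of the 5 aged libraries only aged unwounded and aged 7 dpw replicate 2 share the batch of the young ones. Col14a1 (3.70), Tnc (2.69) and Bgn (2.23) rose at 4.95, 1.73 and 1.20% of their highest class. Krt6a (1.06 ± 1.85, adjusted p = 0.946), Krt16 (1.32, adjusted p = 0.762) and Krt17 (1.19 ± 0.34, adjusted p = 0.211) were not called. Krt15 fell over its list alone, named after the values were seen (8030 ± 4020 to 4260 ± 2600 CPM, -1.10, adjusted p = 0.0525 over all genes).

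Of 23 lists, 8 were called for age in basal keratinocyte-like cells, 0 with an estimated correlation and 5 without aged 7 dpw replicate 2. Wound keratinocyte genes rose (1 of 21 called, 9 when adjusted over the list alone; median 1.13, adjusted p = 6.91e-06; adjusted p = 0.157 with an estimated correlation), with Cd44 (0.84), Hbegf (1.05) and Tgfa (1.73) among the list-alone rises. Myofibroblast (median 1.22, adjusted p = 1.01e-05; adjusted p = 0.157 with an estimated correlation), fibrillar matrix (0.91, adjusted p = 1.21e-05), matrix remodelling (1.07, adjusted p = 3.27e-05) and senescence genes (0.96, adjusted p = 0.00729) rose. The last 3 had an adjusted p = 0.359 with an estimated correlation. For the myofibroblast and matrix lists, free RNA of other cells was not excluded, as the low levels of Col14a1, Tnc and Bgn given above show. Inflammatory (median 0.43, adjusted p = 0.0328; adjusted p = 0.364 with an estimated correlation) and glycolysis genes (0.19, adjusted p = 0.0154; adjusted p = 0.524 with an estimated correlation) rose, and dissociation genes fell (-0.29, adjusted p = 0.0271; adjusted p = 0.359 with an estimated correlation). The 36 calls became 7 without the batch block, 317 without a filter on low counts, 14 with thinned depth, 119 at resolution 2, 20 with free RNA genes left out, 104 in batch 2 alone and 73 with the v2 libraries. Leaving out 1 library gave 0 without young unwounded replicate 1, 12 without young 4 dpw replicate 1 and 16 without aged 4 dpw replicate 1. It gave 23 without aged unwounded replicate 2, 65 without aged 7 dpw replicate 2 and 141 without aged 7 dpw replicate 1.

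Macrophage-like cells of the wound expressed more Arg1, an enzyme known from repair-type macrophages, and less of the lectin genes Mgl2 and Cd209a. Mgl2 fell from 616 ± 83.7 to 6.02 ± 3.16 CPM at 4 dpw (n = 2 and 3; log2 FC -6.93 ± 0.59, adjusted p = 0.00779) and to 13.6 ± 6.31 CPM at 7 dpw (n = 3; -5.69 ± 0.54, adjusted p = 0.018). Cd209a fell from 277 ± 292 to 1.08 ± 0.335 CPM (-7.90 ± 0.84, adjusted p = 0.018) and to 1.44 CPM (-7.19 ± 0.76, adjusted p = 0.0207). Arg1 had 1 count in unwounded and 20416 counts in 4 dpw cells, a ratio of 289 with a counting interval of 51.8 to 11400 (adjusted p = 0.00779). It had 8901 counts at 7 dpw (ratio 284, interval 50.9 to 11200, adjusted p = 0.018). Over all v3 libraries pooled, Mgl2 and Cd209a stood at 2.12 and 0.849% of the class where each is highest. Those percents rest mostly on wound cells. In unwounded skin Mgl2 was at 616 CPM here against 1390 ± 186 CPM in dendritic-like cells. Cd209a is a fixed dendritic and Arg1 a fixed macrophage marker.

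At 4 dpw 7 of 10516 genes changed, named here after the values were seen: Arg1, Mgl2, Cd209a, Cd81 (-4.11 ± 0.52, adjusted p = 0.0475), Cd209b, Cd209f and Cd209g. Cd209b and Cd209f fell (each 1 against 36 counts, 2540-fold lower, interval 428 to 103000, adjusted p = 0.00976 and 0.0166), as did Cd209g (0 against 25 counts, at least 589-fold lower, adjusted p = 0.0475). At 7 dpw 5 changed: Arg1, Mgl2, Cd209a, Cd209b (1 against 36 counts, 1130-fold lower, interval 190 to 45900, adjusted p = 0.0207) and Retnla (1 against 518 counts, 16300-fold lower, interval 2910 to 643000, adjusted p = 0.0207). Il1b (1.24, adjusted p = 0.368 at 4 dpw and 1.45, adjusted p = 0.381 at 7 dpw) and Mrc1 (-2.33 ± 0.62, adjusted p = 0.191 and -2.38, adjusted p = 0.276) were not called. Neither were Cxcl2 (1.07 and 1.28, adjusted p = 0.483 at 7 dpw) and Ccl2 (-1.33, adjusted p = 0.536 and -1.74, adjusted p = 0.501). The unwounded side held 49 and 23 cells in its 2 libraries, 42 and 22 of them in cluster 3. At 4 dpw cluster 9, led by Arg1, held 52.0 and 41.6% of the aged and 19.9% of the young cells, and cluster 19 held 33.0% of the young ones, so the wound contrasts also compare different clusters.

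The repair-type list fell at 4 dpw (1 rose and 0 fell of 22, and 3 rose and 8 fell when adjusted over the list alone; median log2 FC -1.28, adjusted p = 0.0109; adjusted p = 0.741 with an estimated correlation). At 7 dpw it was not called (1 rose, 1 fell, median -0.53, adjusted p = 0.0683). MHC class II presentation fell in macrophage-like cells at 4 dpw (0 of 7 called, all 7 when adjusted over the list alone; median log2 FC -3.68, adjusted p = 9.55e-08; adjusted p = 0.741 with an estimated correlation). It also fell at 7 dpw (median -2.32, adjusted p = 5.24e-06; adjusted p = 0.947 with an estimated correlation). H2-Aa (-3.68, 6000 to 497 CPM) and Cd74 (-3.66, 14200 to 1200 CPM) led it at 4 dpw, at 5.7 and 5.5% of their highest class. Those percents pool all v3 libraries, mostly wound cells, so they do not describe the unwounded level. Complement fell (median -1.68 and -1.47 with low-count genes at their bound, adjusted p = 0.000296) and glycolysis and hypoxia rose (median 1.23 with such genes at the bound, adjusted p = 0.000461), each with an adjusted p = 0.741 with an estimated correlation. Over single lists, named after the values were seen, C1qa (-2.11), Cd163 (-5.31) and Igf1 (-3.18) fell and Il1a (4.37), Cxcl1 (3.98), Hif1a (2.19), Vegfa (1.91) and Gpnmb (1.90) rose at 4 dpw. The inflammatory list was not called (median 1.16 and 0.92 at the bound, adjusted p = 0.173).

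The macrophage wound counts rest on few cells. The count of 7 at 4 dpw became 316 by DESeq2, 626 without a filter on low counts, 78 without the batch block and 1 with a stricter cell filter. It was 219 with a looser mitochondrial filter, 4 at resolution 2 or with free RNA genes left out, 35 in batch 2 alone, 130 with the v2 libraries and 471 without cluster 19. Leaving out 1 library gave 0 without aged unwounded replicate 1, 1 without young unwounded replicate 1, 42 without aged 4 dpw replicate 2 and 56 without aged 7 dpw replicate 2. It gave 69 without aged 7 dpw replicate 1, 70 without young 4 dpw replicate 1, 136 without young 7 dpw replicate 3 and 703 without aged 4 dpw replicate 1. The count of 5 at 7 dpw became 189 by DESeq2 and 384 without a filter on low counts. It was 0 with a stricter cell filter or in batch 2 alone, 82 with a looser mitochondrial filter, 3 with free RNA genes left out, 11 with the v2 libraries and 305 without cluster 19. It became 0 without aged unwounded replicate 1, and 1 without young unwounded replicate 1 or aged 7 dpw replicate 1. It was 18 without aged 4 dpw replicate 2, 19 without aged 7 dpw replicate 2, 34 without young 7 dpw replicate 3, 89 without young 4 dpw replicate 1 and 225 without aged 4 dpw replicate 1.

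With age, macrophage-like cells had more reads of Serpinb2, a protease inhibitor gene that activated macrophages are known to induce. Serpinb2 rose from 20.0 ± 14.3 CPM in young (n = 3) to 313 ± 193 CPM in aged libraries (n = 5; log2 FC 3.98 ± 0.35, adjusted p = 0.0186). It stood at 7.57% of the class where it is highest, a level that free RNA can give. It is named because the count is 1 of 10516. Arg1 stood at 1200 ± 871 against 81.7 ± 79.3 CPM and did not pass (3.53 ± 0.39, adjusted p = 0.0628). Its level was 2345 and 1639 CPM in the aged and 158.4 CPM in the young 4 dpw libraries, and 894.2 and 1097 CPM against 86.79 CPM at 7 dpw. Il1b (0.61), Mrc1 (0.93), Cxcl2 (1.06) and Ccl2 (1.10) had an adjusted p = 0.996. Ereg was at 112 against 4.05 CPM (4.03 ± 0.58, adjusted p = 0.236). At unadjusted p < 0.05 there were 400 genes. Of the 5 aged libraries only aged 4 dpw and aged 7 dpw replicate 2 share the batch of the young ones. Cluster 19, led by Atp6v0d2, Acp5, Mmp9 and Ocstamp, held 33.0% of the macrophage-like cells of the young 4 dpw library and 1.9 and 7.1% in the aged ones. At 7 dpw it made up 3.94 and 0.36% of all cells in the aged and 0.31% in the young v3 library.

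Of 23 lists, 17 were called for age in macrophage-like cells, 0 with an estimated correlation, 11 without aged 7 dpw replicate 2 and 3 without young 4 dpw replicate 1. Oxidative phosphorylation fell (median log2 FC -0.65, 0 of 23 members positive, adjusted p = 2.53e-08). Wound keratinocyte (1.30, adjusted p = 2.53e-08), repair-type (0.76, adjusted p = 1.24e-05), inflammatory (0.63, 18 of 18 positive, adjusted p = 2.47e-05) and glycolysis genes (0.29, adjusted p = 0.000497) rose. Each of these 5 lists had an adjusted p = 0.493 with an estimated correlation. The other 12 called lists rose in the main fit, and 6 of them turned in at least 1 alternative: interferon-stimulated, fibrillar matrix and receptors without the batch block, interferon-stimulated, complement, receptors and dissociation without young 4 dpw replicate 1, and haemoglobin without aged 4 dpw replicate 2. Epidermal differentiation (median 1.45, adjusted p = 0.000883), fibroblast chemokines (0.78, adjusted p = 0.00118), senescence (0.51, adjusted p = 0.00118), myofibroblast (0.50, adjusted p = 0.00118), matrix remodelling (0.45, adjusted p = 0.00209) and growth factor ligands (0.32, adjusted p = 0.00527) had an adjusted p = 0.493 with an estimated correlation as well. Complement (0.47, adjusted p = 0.00722), fibrillar matrix (0.39, adjusted p = 0.00527) and receptors (0.20, adjusted p = 0.0347) had an adjusted p = 0.623 with an estimated correlation. Interferon-stimulated (0.36, adjusted p = 0.0347) and dissociation genes (0.29, adjusted p = 0.0129) had an adjusted p = 0.653 with an estimated correlation. Haemoglobin genes (2.14, adjusted p = 0.0361) had an adjusted p = 0.548 with an estimated correlation. For the keratinocyte, epidermal, fibroblast and matrix lists among these, free RNA of other cells was not excluded. In aged wound macrophage-like cells, 10 abundant basal keratinocyte genes, Krt14 among them, stood at a median of 0.447% of their basal level. The single call became 25 by DESeq2, 118 without a filter on low counts, 7 in batch 2 alone and 0 with a stricter cell filter or with free RNA genes left out. It was 2 without the batch block, with thinned depth, with the v2 libraries, with a looser mitochondrial filter or without cluster 19. It became 0 without aged unwounded replicate 1, young 4 dpw replicate 1 or young unwounded replicate 1, and 2 without aged 4 dpw replicate 2 or young 7 dpw replicate 3. It was 4 without aged 7 dpw replicate 2, 7 without aged 7 dpw replicate 1 and 73 without aged 4 dpw replicate 1.

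**Figure D3:**
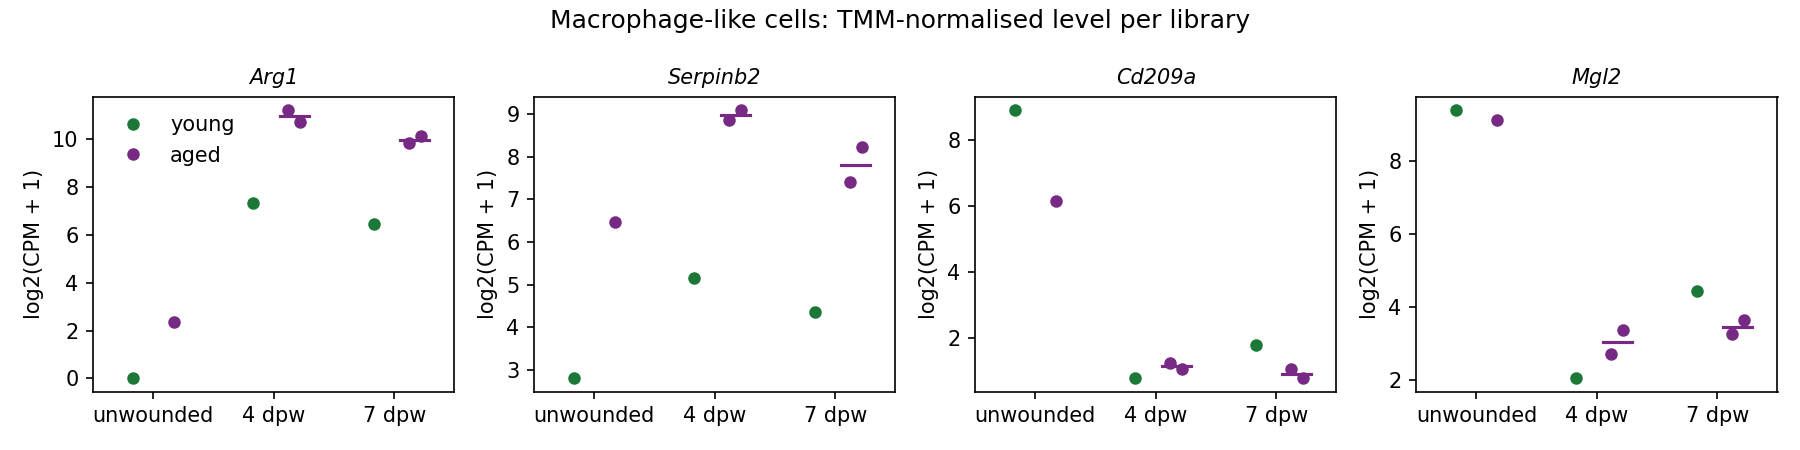
Levels of 4 genes in macrophage-like cells of each v3 library; green, young; purple, aged; the line is the mean of the 2 aged libraries.

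Whether the wound response differs with age was tested directly as an interaction, since delayed repair in aged skin is well known. In fibroblast-like cells 0 of 15274 genes were called by edgeR (997 at unadjusted p < 0.05; 127 by DESeq2; 9 without a filter on low counts). Leaving out aged unwounded replicate 1 gave 18, aged 4 dpw replicate 1 gave 5, and aged 4 dpw replicate 2 or aged 7 dpw replicate 2 gave 4. In basal keratinocyte-like cells 0 of 8907 were called (194 at unadjusted p < 0.05; 2 by DESeq2). There were 52 without a filter on low counts, 51 with a stricter cell filter, 29 with thinned depth, 8 with a looser mitochondrial filter and 1 with doublets kept or with free RNA genes left out. In macrophage-like cells 0 of 11415 were called (658 at unadjusted p < 0.05; 18 by DESeq2). There were 98 without a filter on low counts, 18 with a looser mitochondrial filter and 6 without cluster 19. With 2, 1 and 1 residual degrees of freedom, 0 of 200 genes raised 4-fold in simulated aged 7 dpw libraries were recovered, so a call of 0 does not exclude such a difference.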

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

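Of the tests here, the cluster mix of Arg1 and Serpinb2 and the source of Arg1 RNA were written down before their values were seen, and all others were chosen after results were seen. Arg1 and Serpinb2 were taken out of the source lists after a first look.

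Arg1 and Serpinb2 were higher in aged macrophage-like cells, which might come from a different mix of clusters. Within clusters 3 and 9 the Arg1 log2 FC was 2.72 ± 0.37 (adjusted p = 0.0444) and 2.12 ± 0.52 (adjusted p = 0.25) by edgeR, against 3.53 over the whole class. Serpinb2 was 2.45 ± 0.46 (adjusted p = 0.206) and 1.91 ± 0.41 (adjusted p = 0.122), against 3.98. The mix was to be argued against if the lowest cluster value exceeded 0.5 of the class-wide value by more than its standard error, which neither gene met, so the mix stays open. RNA from other cells was judged by the level of each gene relative to 4 possible source classes. Arg1 reached at least 1740 and Serpinb2 at least 3.0 times the highest value of 10 abundant genes of that source. Those genes were chosen to be at least 10 times higher in the source, which favours passing. Arg1, at 1370 CPM in aged wound macrophage-like cells against at most 8.23 CPM in the sources, argues against RNA from them. Serpinb2 stood at 9.66, 23.6 and 47.6% of the basal, spinous and fibroblast-like levels. For it the test decides nothing, and free RNA stays open. For a batch or kit difference, the log2 FC in batch 2 alone was 3.51 for Arg1 and 3.96 for Serpinb2. The young and aged libraries there share batch and kit, so these values argue against a difference of the labelled batch or kit. They are no separate support, because the main fit also estimates age within batch 2. Other differences between the libraries of that batch were not tested.

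Follicle clusters 21, 25 and 31, led by Top2a, Krt35 and Krt71, made up 216 of 3959 (5.46%, 4.77 to 6.21) and 660 of 3659 cells (18.04%, 16.8 to 19.32) in the aged unwounded libraries and 0 of 3625 in the young one, where a count of 0 allows 0.083%. A generally higher follicle yield is argued against, as these clusters differed by ratios of at least 28.7 and 117 more than the other follicle clusters (11.54 and 9.37% against 5.02%). In wounds they were 1.96 and 0.09% (aged 4 dpw), 1.25 and 4.76% (aged 7 dpw), 0.03% (young 4 dpw), 0.06% (young 7 dpw, v3) and 0.11 and 0.17% (v2). There was 1 young unwounded library, but every young library held at most 0.17%, as did 1 aged 4 dpw library (0.09%). The hair-cycle phase was not measured here. It could differ between the ages as a whole, not only in that 1 library, and stays open as the cause.

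Cluster 19, led by Atp6v0d2, Acp5, Mmp9 and Ocstamp, made up 387 of 3677 cells (10.52%, 9.55 to 11.56) of the young 4 dpw library. It made up 0.59 and 1.87% in aged 4 dpw, 3.94 and 0.36% in aged 7 dpw, and 0.31, 1.19 and 1.22% in young 7 dpw libraries. Doublets could explain it: its median UMI was 30069 against 8678 over all cells, but 4.08% of it was called a doublet against 4.62% overall. For 10 osteoclast genes chosen after the cluster was seen, such as Ctsk and Acp5, the level over the highest other cluster had a median of 3.83, and of 1.49 over the 5 that do not lead the cluster, which leaves doublets open. There is 1 young 4 dpw library, so a chance difference of that library also stays open.

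Some young and aged libraries moved in opposite directions, a difference that was not tested gene by gene beyond the interaction, and no group had enough libraries for an outlier test. For Cdkn2a in fibroblast-like cells, the log2 change from unwounded skin was 1.31 in young and -2.05 and -1.09 in aged libraries at 4 dpw, and 1.99 against -1.66 and -1.56 at 7 dpw. The counts behind it were 30 in young and 681 and 966 in aged unwounded skin. The hair follicle keratinocyte share at 7 dpw changed by 0.16 in young and -0.92 and -0.68 in aged libraries, and the pericyte share at 4 dpw by -0.52 in young and 1.34 and 0.81 in aged ones.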

How the results depend on the processing

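Of the gene results that passed, 319 with 6698 alternative values, 5909 stayed the same, 789 were weaker and 0 reversed. Of 102 that did not pass, 2133 values, 1779 stayed, 333 were stronger and 21 reversed, in 13 results. Among those that passed, the largest rises and falls had to keep their sign in every fit without 1 library. Those fits could thus not reverse them. For shares, 173 of 180 values of the 10 called stayed and 7 were weaker, and all 36 of the 2 uncalled stayed. The cause was not tested for any moved or reversed result. Counts follow in the order fibroblast-like, basal keratinocyte-like, macrophage-like, with "main" values 1, 36 and 1 (age), 4869, 26 and 7 (4 dpw), 2904, 96 and 5 (7 dpw) and 0, 0 and 0 (interaction).

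DESeq2 gave 230 and 25 for age (fibroblast-like and macrophage-like), 41 and 316 at 4 dpw (basal and macrophage-like), 189 at 7 dpw (macrophage-like) and 127, 2 and 18 for the interaction. No filter on low counts gave 48, 317 and 118 for age, 307 and 626 at 4 dpw, 558 and 384 at 7 dpw (basal and macrophage-like) and 9, 52 and 98 for the interaction. Without the batch block, which ends the pairing of the aged libraries, age gave 40, 7 and 2, 4 dpw 3 and 78, and 7 dpw 23 (basal). Thinned depth gave 0, 14 and 2 for age, 2 at 4 dpw, 52 at 7 dpw and 29 for the interaction (basal). Resolution 2 gave 0 and 119 for age and 4 at 4 dpw (macrophage-like). Leaving out free RNA genes gave 0, 20 and 0 for age, 16 and 4 at 4 dpw, 3 at 7 dpw (macrophage-like) and 1 for the interaction (basal). Batch 2 alone gave 0, 104 and 7 for age, 1640 and 35 at 4 dpw (fibroblast-like and macrophage-like) and 129, 179 and 0 at 7 dpw. The v2 libraries gave 6, 73 and 2 for age, 130 at 4 dpw (macrophage-like) and 194 and 11 at 7 dpw (basal and macrophage-like).

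The stricter cell filter gave 0, 1 and 0 in macrophage-like cells (age, 4 and 7 dpw) and 51 for the basal interaction, and doublets kept gave 1 there. The looser mitochondrial filter, chosen after the data were seen, gave 2, 219, 82 and 18 in macrophage-like cells (interaction last) and 8 for the basal interaction. Without cluster 19, also chosen later, macrophage-like cells gave 2, 471, 305 and 6. Leaving out 1 library gave, for age, 0 to 1, 0 to 141 and 0 to 73; at 4 dpw 1987 to 5410, 2 to 137 and 0 to 703; at 7 dpw 832 to 3519, 25 to 153 and 0 to 225; and 0 to 18 for the fibroblast interaction. Shares were called in 0 classes for age throughout, in 10 at 4 dpw with doublets kept, 5 to 10 at 4 dpw and 4 to 5 at 7 dpw without 1 library, and 0 at 7 dpw by exact permutation, whose arrangements also move the 4 dpw libraries. An estimated correlation called 0 lists in each class, and leaving out 1 library gave 9 to 13, 5 to 10 and 3 to 20 lists.

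Reversed in fibroblast-like cells were Cdkn1a with age (0.06 without the batch block, 0.01 without young unwounded replicate 1, range -0.43 to 0.01), Acta2 with age without aged unwounded replicate 2 (range -0.20 to 2.79), Col1a1 at 7 dpw without aged unwounded or aged 7 dpw replicate 2 (-0.15 and -0.13, range -0.15 to 0.43) and at 4 dpw without aged unwounded replicate 1 (range -0.56 to 0.02). In basal cells these were Krt16 at 4 dpw (0.03 at resolution 2, range -3.01 to 0.30, the last without aged 4 dpw replicate 1), Krt17 at 7 dpw (-0.67 at resolution 2, -0.01 without aged unwounded replicate 1, -0.02 without young 7 dpw replicate 3, range -0.02 to 0.87), Krt6a with age (-0.84 without aged unwounded replicate 2, -1.19 without young 7 dpw replicate 3, range -1.19 to 3.49), Krt16 with age without aged unwounded replicate 2 (range -0.68 to 2.33) and Krt6a at 4 dpw without young 4 dpw replicate 1 (range -0.86 to 7.36). In macrophage-like cells these were Ccl2 at 4 and 7 dpw (0.60 and 0.43 with the stricter filter; without young unwounded replicate 1, ranges -2.84 to 0.81 and -3.05 to 0.62), Cxcl2 at 4 dpw in batch 2 alone (-0.02) and Il1b with age without young 4 dpw replicate 1 (range -0.05 to 1.12). Their age lists turned without the batch block for interferon-stimulated (adjusted p = 0.991), fibrillar matrix (0.0344) and receptors (0.514), without young 4 dpw replicate 1 for interferon-stimulated (range of adjusted p 0.0022 to 0.737), complement (0.000192 to 0.88), receptors (0.00647 to 0.88) and dissociation (1.98e-05 to 0.374), and without aged 4 dpw replicate 2 for haemoglobin (0.0301, range 1.02e-13 to 0.519). The interaction could not be fitted in batch 2 alone, with the v2 libraries, when a young library was left out, at resolution 2 in basal or with the stricter filter in macrophage-like cells.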

Other observations

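Of the tests in this part, the splits of T-cell-like, spinous keratinocyte-like and dendritic-like cells were written down before their values were seen; the other splits were chosen after results were seen.

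T-cell-like cells of aged skin expressed less Foxp3 and Ctla4, genes of regulatory T cells, which restrain inflammation in skin, named here after the values were seen. Foxp3 fell from 258 ± 55.5 CPM in young (n = 3) to 94.8 ± 33.2 CPM in aged libraries (n = 6; log2 FC -1.13 ± 0.19, adjusted p = 0.00325), with Ctla4 (-1.10 ± 0.23, adjusted p = 0.0134), Ikzf2 (-1.24), Il10 (-1.70) and Gzmb (-1.57). Tnfsf8 rose from 47.6 ± 15.3 to 390 ± 296 CPM (3.30 ± 0.34, adjusted p = 3.74e-05), with Tnfsf11 (2.13), Calca (1.97), Cd40lg (1.67), Cd163l1 (1.64) and Cxcr6 (1.02). Cluster 16, led by Ctla4 and Foxp3, held 52.0, 30.3 and 61.4% of young and 16.7 to 24.8% of aged T-cell-like cells. Tnfsf8, Tnfsf11, Cd40lg and Cxcr6 are among the leading genes of a cluster of 182 T-cell-like cells at resolution 2, of which 63.2% came from aged unwounded replicate 2. No fit within clusters was made, so neither the falls nor the rises were tested within a cluster. In all 128 of 9085 genes changed with age, 196 at 4 dpw, where Gimap4 (2.61), Gimap5 (2.20), Gimap3 (1.98) and Gimap6 (1.80) rose, and 86 at 7 dpw, where Gimap4 (1.96) and Il1rl1 (1.18) rose and Il13 (-1.98) and Il2 (-1.47) fell. By DESeq2 the counts were 57, 91 and 43, without the batch block 33, 27 and 4, and without 1 library 36 to 169, 36 to 224 and 19 to 106.

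Spinous keratinocyte-like cells expressed more Krt6a and Krt16, which suprabasal wound epidermis is known to express, at 7 dpw and with age. Krt6a rose from 5.90 ± 5.44 to 1080 ± 961 CPM at 7 dpw (n = 3 and 3; 7.78 ± 0.52, adjusted p = 1.14e-06), with Stfa1 (6.61), F3 (4.97), Krt16 (3.00), Fabp5 (3.00) and Krt17 (2.56), while Krt15 (-2.61), Cxcl14 (-1.97) and Il34 (-1.50) fell (1111 genes; 199 at 4 dpw). With age Krt6a went from 73.1 ± 117 to 713 ± 869 CPM (n = 3 and 5; 3.05 ± 0.52, adjusted p = 0.0174) and Il33 from 95.7 to 351 CPM (1.70 ± 0.18, adjusted p = 0.000727), with Krt17 (2.04), Krt16 (1.65), Casp4 (2.32) and Epgn (2.27) also up, 77 genes in all. These cells sat in different clusters: cluster 26, with Krt16, Krt6a, Stfa1 and Fabp5 among its leading genes, held 0.5 to 3.8% of the class in unwounded skin, 71.7 and 70.5% in aged and 21.9% in young 7 dpw libraries of the v3 kit, so the rises of these genes and the share of that cluster are not separate results. The age count was 31 with doublets kept, 41 without the batch block, 528 in batch 2 alone and 38 to 138 without 1 library. The 7 dpw count was 579 without the batch block and 419 to 1459 without 1 library. Dendritic-like cells changed 1373 genes at 4 dpw (782 up) and 185 at 7 dpw, with Il12b (4.39), Cd200 (3.81) and Il4i1 (3.24) up and Mgl2 (-2.17), Cd163 (-3.56) and Ccl2 (-2.83) down at 4 dpw. Cluster 29, with Ccl22, Il4i1 and Ccr7 among its leading genes, held 2.0 to 9.5% of these cells in unwounded skin and 20.3 to 39.2% at 4 dpw, and Mgl2 leads the other main cluster, 10, so these changes are not separate from that mix. Their age count was 0 by edgeR, with 414 genes at unadjusted p < 0.05. Their 4 dpw count was 629 to 1342 and their 7 dpw count 2 to 300 without 1 library.

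Other ways of dividing the same libraries were fitted to see how many genes they call. The age splits move libraries across times and batches, so their shares are not an exact chance rate. For age, at least as many genes were called in 4 of 80 splits for fibroblast-like (1 gene; highest other 15), 2 of 53 for basal keratinocyte-like (36; 48), 2 of 80 for T-cell-like (128; 128) and 1 of 53 for spinous keratinocyte-like cells (77; 42), each counting the real one. For macrophage-like cells it was 5 of 53 (1 gene). The split that set aged 7 dpw replicate 1, aged unwounded replicate 1 and young 4 dpw replicate 1 apart called 1257. What gave that count was not tested. The T-cell split with 128 sets the 3 aged batch 2 libraries apart, the same contrast mirrored. The basal split with 48 sets aged unwounded replicate 2, aged 7 dpw replicate 2 and aged 4 dpw replicate 1 apart. Within batch 2 it is also the real contrast mirrored. The time contrasts had only 10 splits, too few for a share under 0.05. Their other splits mix wounded and unwounded libraries in both groups. The wound change then counts as spread within groups, so low counts there do not measure chance. The real and highest other counts were 4869 and 0 (fibroblast-like, 4 dpw), 2904 and 0 (7 dpw), 96 and 8 (basal, 7 dpw), 196 and 3 (T-cell-like, 4 dpw), 86 and 1 (7 dpw), 1111 and 0 (spinous, 7 dpw), 1373 and 0 (dendritic-like, 4 dpw) and 185 and 0 (7 dpw), the real one being 1 of 10.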
